A study of Mus musculus with 10 samples.

How the data were processed

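RNA was measured by bulk sequencing in the micro-dissected dentate gyrus, the hippocampal subfield of granule neurons, from 10 male C57BL/6 mice aged 10 weeks. The mice were 5 wild types and 5 knockouts of Fndc5, the gene of the irisin precursor. Per the labels' protocols, RNA was isolated with Trizol and a column kit, stranded poly(A) libraries were made from 500 ng of total RNA, and single-end reads of 75 bases were taken on a NextSeq500. The deposited table holds raw read counts per gene symbol, with no normalization, for 24982 rows. Per the submitters' processing notes, STAR 2.5.1b, Cufflinks 2.2.1 and the genome build mm10 were used, and the notes give no role or order for these tools. The strand setting of the counting and the treatment of reads that map to several places are not given in the sources used here. Reads of overlapping or antisense genes, and of near-identical families such as ribosomal protein genes with their pseudogene copies, Hspa1a with Hspa1b, or Mt1 with Mt2, may therefore be split or lost, and their levels are uncertain.

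Symbols in the table are in upper case. Of these, 24853 matched a RefSeq (GRCm38.p6) or GENCODE M21 symbol, 60 matched a synonym and 69 matched none, and coordinates are from GRCm38, 1-based. The table had 0 rows for the 13 mitochondrially encoded genes, and 1 of the 8 blood cell genes passed the low-count filter, fewer than the 3 members a list needed, so both of those lists were left untested.

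Groups were taken from the genotype label of each mouse, and 1 mouse gave 1 library. The depth ranged from 26226375 to 43802079 counts per library. No pair of libraries of a genotype agreed within sampling noise (lowest chi-square over degrees of freedom 4.89 for a pair), so each counted as 1 replicate. Y-linked Ddx3y was counted in every library and Xist had at most 5 counts.

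Genes were filtered with filterByExpr, which left 14867, libraries were scaled by TMM, and genotypes were compared with edgeR 4.0.16 (glmQLFit and glmQLFTest) in R 4.3.3. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, with a threshold of 0.05. Standard errors were taken from the fold change and its F statistic, and 95% intervals from the t distribution with the fit's degrees of freedom. Single values of 5 against 5 mice were compared by exact two-sided permutation over the 252 ordered assignments, for which the smallest p is 0.00794. Of 35 gene lists fixed for testing, 33 had at least 3 tested members and entered limma 3.58.1 camera on log2 CPM with a prior count of 2 and a preset correlation of 0.01. Camera with an estimated correlation and fry were run beside it, and list p-values were adjusted over the lists. A further list of sex-linked genes served only as a check. The design, the gene lists and the rule for naming genes were fixed before the data were examined. The rule takes Fndc5, then, where fewer pass the threshold, the 20 genes beyond Fndc5 with the smallest p, passing over predicted genes and pseudogenes (names with Gm and a number, Rik or -ps), and up to 4 members of each list with the smallest p; other genes named were chosen after their values were seen. Some list members that the rule takes are not reported here.

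The steps were tested on simulated counts for this comparison, with 14806 genes tested. Changes of 1.25-fold were recovered for 55.2% of 67 genes, 1.5-fold for 83.6% of 67 and 2-fold for 96.9% of 65, and 6 unchanged genes were called. The 95% intervals held the true value for 95.2% of genes. A list of 25 genes shifted by -0.18 on the log2 scale was found by camera, and 0 of 40 unchanged lists were called. Simulated genes vary independently, which real gene lists do not. Many genes were changed at once, which eases the adjusted threshold, so recovery would be lower where few genes change.

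Alternatives were DESeq2 1.42.0 (Wald test and size factors), upper-quartile scaling, no low-count filter, a filter of 1 CPM in 5 libraries, the mouse number as a block, each library left out in turn, limma-voom and voom with sample quality weights. Spline corrections of each library for GC content and transcript length (4 degrees of freedom each), and removal of the ribosomal RNA precursor row, which held 0.603% to 1.85% of counts, were added after seeing the data.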

Results

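The dentate gyrus transcriptome was compared between 5 wild-type mice and 5 mice with a global knockout of Fndc5, which encodes the membrane protein cleaved to the secreted myokine irisin. Each mouse gave 1 library of 26226375 to 43802079 counts. The comparison asks which transcripts of this hippocampal region differ when Fndc5 is disrupted.

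Fndc5 was lower in every knockout mouse than in every wild-type mouse. The gene lies on chromosome 4 from 129136870 to 129144593 (GRCm38). Its level was 75.3 ± 4.60 CPM in wild types and 51.3 ± 4.27 CPM in knockouts (mean ± SD, n = 5 each), with libraries between 69.2 and 80.3 CPM and between 45.4 and 56.7 CPM. The log2 fold change was -0.55 (SE 0.057, 95% interval -0.67 to -0.43), with an edgeR adjusted p of 0.000495 and an exact permutation p of 0.00794, the smallest this design allows. The knockouts kept 68.1% of the wild-type Fndc5 counts (95% interval 62.7% to 74.0%). The table has 1 count per gene and does not show which exons those reads come from.

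**Figure D1:**
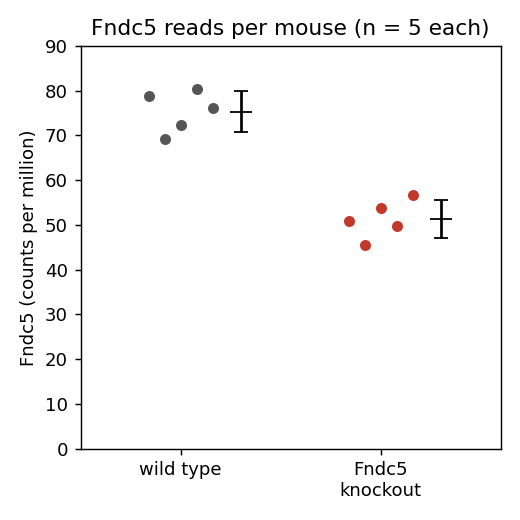
Fndc5 level (CPM) for each mouse (points) with the mean and SD beside them, for 5 wild-type and 5 Fndc5 knockout mice. Knockout mice lie between 45.4 and 56.7 CPM and wild types between 69.2 and 80.3 CPM.

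Fndc5 was the only 1 of 14867 genes past the threshold in the edgeR fit, with 0 genes higher and 1 lower in the knockout. The next smallest adjusted p was 0.56. At an unadjusted p under 0.05 there were 935 genes, of which 378 were higher and 557 lower, against 743 expected by chance. With single libraries left out that number ranged from 557 (without wild-type mouse 2) to 1234 (without knockout mouse 2). Of 100 splits of the libraries into 5 and 5, the real one included, 26 had at least as many. No excess over chance can therefore be read from the number with genotype alone in the model. With the mouse number as a block it was 1493, and the splits were made without that block, so they do not bear on it. Under upper-quartile scaling, with genotype alone, 57.4% of the genes at an unadjusted p under 0.05 were higher, against 40.4% with TMM. No direction can therefore be read from the counts of higher and lower genes. The DESeq2 Wald test called 3 genes, adding Npas4 and Fosb to Fndc5. The median 95% interval reached 0.14 on the log2 scale to either side, and the interval lay within 1.5-fold in both directions for 90.1% of genes and within 2-fold for 98.5%.

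The genes with the next smallest p-values did not pass over all genes in edgeR with genotype alone in the model. Among them Npas4, an activity-dependent transcription factor of neurons, was at 8.0 ± 2.05 CPM in wild types and 4.71 ± 0.567 CPM in knockouts (log2 fold change -0.76, SE 0.15, adjusted p 0.56). Fosb, an AP-1 subunit, was at 8.41 ± 1.03 and 5.91 ± 0.667 CPM (log2 fold change -0.51, SE 0.10, adjusted p 0.56). With DESeq2 the adjusted p was 0.00627 for Npas4 and 0.00815 for Fosb. Without wild-type mouse 1, edgeR gave Npas4 an adjusted p of 0.0176. Crhbp, which binds corticotropin-releasing hormone, had a log2 fold change of -0.74 (SE 0.20) at 3.12 CPM in wild types. Tfrc, the transferrin receptor, had -0.25 (SE 0.058), and the vesicle GTPase gene Rab3c had -0.21 (SE 0.050). Rab3c reached an edgeR adjusted p of 0.0181 without knockout mouse 2. Fosl2, Vps35, Cul2, Ttll7, Acsl4, Ppp1cb, Ugcg, Gnai1, Aff3 and Nus1 had log2 fold changes between -0.21 and -0.14. Higher values were found for Tmprss7 (0.58), Tmem39b (0.23), Acaa1a (0.19), Rreb1 (0.17) and Leng8 (0.12).

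The activity-regulated genes, which neurons transcribe after firing, had lower values in the knockout for 25 of 25 members, with a median log2 fold change of -0.18. Camera placed the list below other genes with the preset correlation (adjusted p 9.0e-11) but not with an estimated correlation (adjusted p = 0.317). Fry, which tests the list against no change, gave an adjusted p of 0.285 for a shift in 1 direction and 0.0328 for change in either direction. Over all genes 0 members passed, and adjusted over the list alone 6 passed: Fosb, Npas4, Fosl2, Fos, Inhba and Nptx2. Fos had a log2 fold change of -0.58 (SE 0.18), Inhba -0.32 (SE 0.097) and Nptx2 -0.32 (SE 0.11), while Egr3 (-0.02), Egr4 (-0.02) and Per1 (-0.05) lay near 0. Those 3 signs turned with single libraries left out. Egr3 was at 0.01 without knockout mouse 1, Egr4 at 0.04 without wild-type mouse 5 and Per1 at 0.0005 without wild-type mouse 4. The list mean per mouse, relative to the wild-type mean, was 0 ± 0.125 in wild types and -0.23 ± 0.0975 in knockouts (exact permutation p 0.0238, adjusted p 0.786 over the lists, where 1 list alone cannot pass with 5 against 5 mice). It was below every wild type in 4 of 5 knockout mice.

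**Figure D2:**
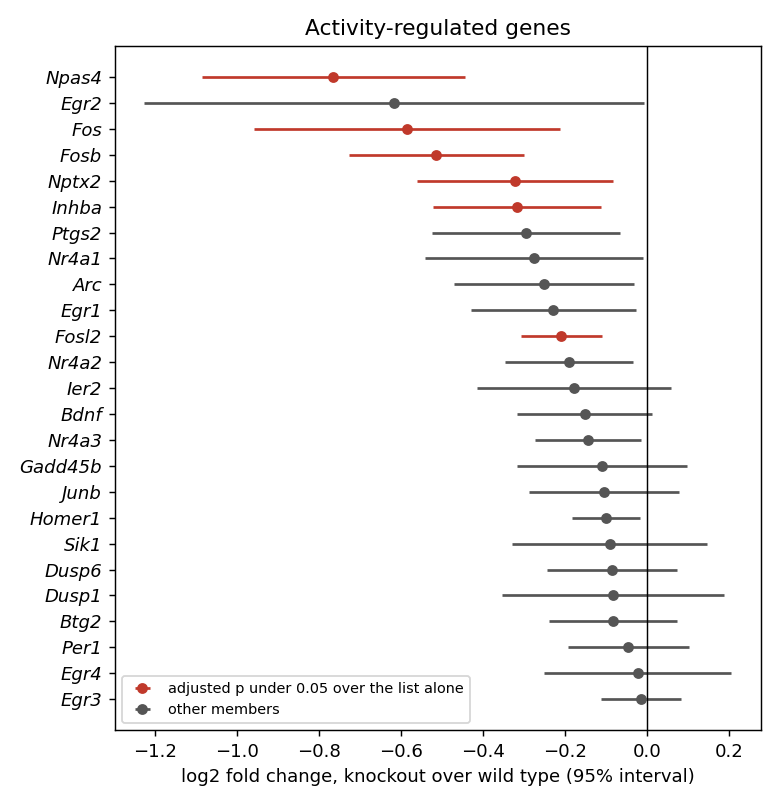
Log2 fold change (knockout over wild type) with 95% interval for the 25 activity-regulated genes. All 25 points lie below 0, and red marks the 6 genes with an adjusted p under 0.05 over the list alone.

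Heat shock and protein folding genes had lower values for 17 of 17 members, with a median log2 fold change of -0.13. Hspe1 was at -0.22 (SE 0.080), Dnaja1 at -0.14 (SE 0.049), Hsp90aa1 at -0.13 (SE 0.047) and Hspd1 at -0.10 (SE 0.040), and no member passed over all genes or adjusted over the list alone. The list passed in camera (adjusted p 0.000122), with an adjusted p = 0.854 with an estimated correlation. Without wild-type mouse 2 the median was -0.08 (camera adjusted p 0.00363). Its wild-type mice spread widely, with an SD of 0.171 for the list mean, against a difference of -0.12 between genotypes (exact permutation p 0.206).

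GABAergic interneuron markers were lower for 14 of 18 members (median -0.10, camera adjusted p 0.00334, adjusted p = 0.854 with an estimated correlation). Among them the GABA synthesis gene Gad1 was at -0.08 (SE 0.035), Dlx1 at -0.28 (SE 0.12) and Vip at -0.30 (SE 0.13). Without wild-type mouse 1 Dlx1 was at -0.14 and Vip at -0.18. GABA-A receptor subunits were lower for 10 of 12 members (median -0.09, camera adjusted p 0.00394, adjusted p = 0.317 with an estimated correlation), with Gabra4 at -0.10 (SE 0.044) and Gabrg1 at -0.19 (SE 0.080). Gabra2 went the other way, at 0.29 (SE 0.18). It was at 0.59 (SE 0.079, edgeR adjusted p 0.00985) without wild-type mouse 1, at 0.19 without mouse 4 and at 0.18 without mouse 5. Neuropeptides were lower for 14 of 18 members (median -0.10, camera adjusted p 0.0297, adjusted p = 0.317 with an estimated correlation), with Scg2 at -0.12 (SE 0.043) and Vgf at -0.10 (SE 0.049, and -0.07 without wild-type mouse 1). With all libraries no member of these lists passed over all genes or adjusted over the list alone. Without wild-type mouse 1 the camera adjusted p was 0.216 for interneuron markers (median -0.06), 0.063 for GABA-A subunits (median -0.10) and 0.063 for neuropeptides (median -0.11). Neuropeptides also lost their call without wild-type mice 4 or 5 or knockout mice 2, 4 or 5 (adjusted p 0.0829, 0.0673, 0.0775, 0.115 and 0.167, with a median of -0.06 without knockout mouse 4), and with no low-count filter (0.0589).

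Cytosolic ribosomal proteins had higher values for 47 of 58 members, with a median of 0.04 on the log2 scale (camera adjusted p 0.00334, adjusted p = 0.854 with an estimated correlation). Rpl36 was at 0.13 (SE 0.054), Rpl15 was at -0.10 (SE 0.041), and no member passed over all genes or adjusted over the list alone. The call was lost without wild-type mouse 1 (median 0.02, adjusted p 0.146), wild-type mouse 5 (median 0.02, adjusted p 0.0673) or knockout mouse 3 (median 0.01, adjusted p 0.372). After correction for GC content and length, added after seeing the data, the adjusted p was 0.116 for ribosomal proteins and 0.147 for GABA-A subunits (median -0.05). The same correction put Vps35 at -0.06, Acsl4 at -0.11, Ppp1cb at -0.10, Dnaja1 at -0.08, Gabra4 at -0.06, Gabrg1 at -0.09, Vgf at -0.15, Dcx at -0.08 and Bdnf at -0.10.

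**Figure D3:**
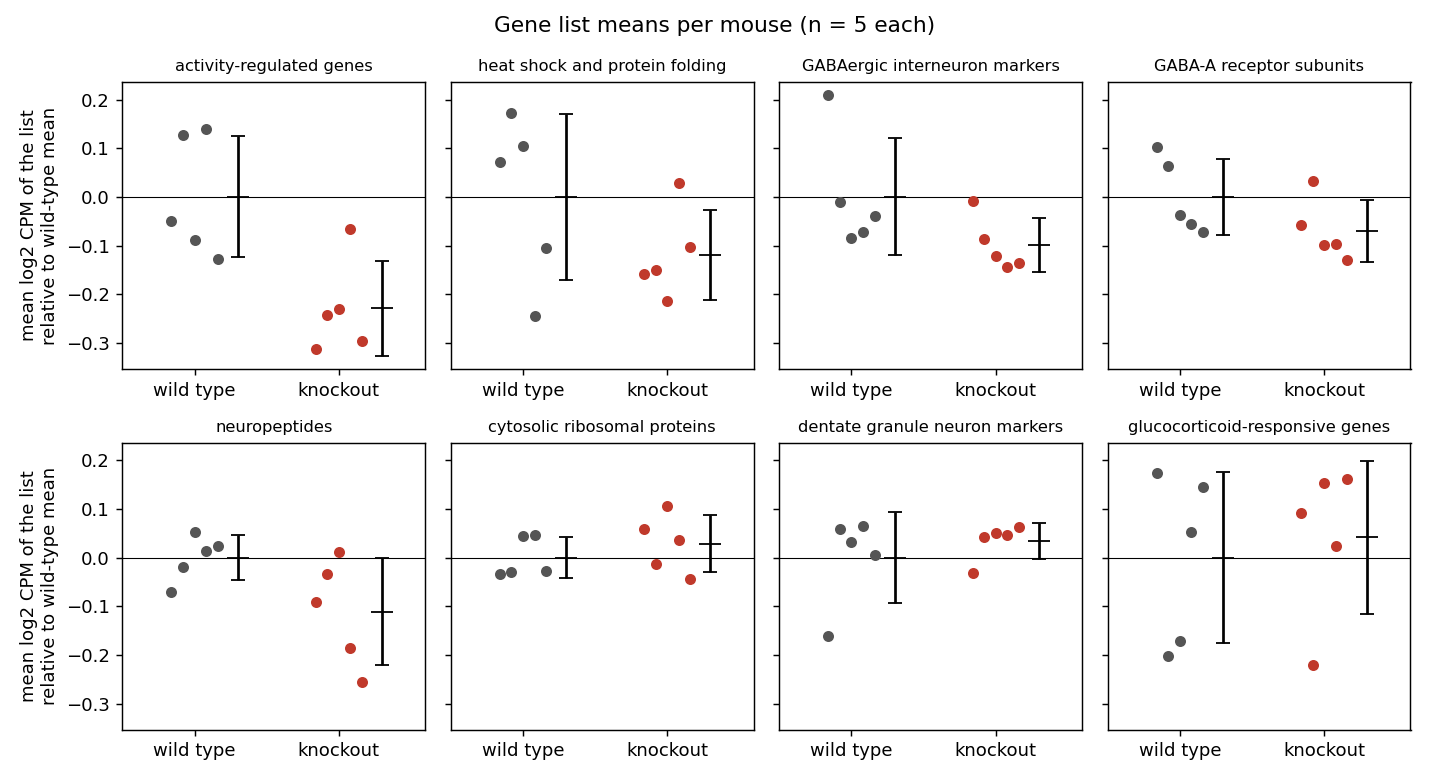
Mean log2 CPM of 8 gene lists in each mouse, relative to the wild-type mean (points), with the mean and SD beside them, for 5 wild-type and 5 knockout mice. Activity-regulated genes lie below every wild type in 4 of 5 knockouts, and wild-type mouse 1 stands apart at 0.209 for interneuron markers and -0.16 for granule neuron markers.

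The other 27 lists did not pass in camera with all libraries. Markers of dentate granule neurons, the main neurons of this tissue, were higher for 11 of 18 members (median 0.03, adjusted p 0.355). Dsp was at 0.16 (SE 0.074) and Lct at 0.12 (SE 0.052), and they were at 0.10 and 0.07 without knockout mouse 5. The list mean was lowest in wild-type mouse 1 (-0.160). The other wild types (0.00459 to 0.0653) overlapped the knockouts (-0.0315 to 0.0635). Immature neuron and neuroblast markers were lower for 13 of 19 (median -0.03, adjusted p 0.513), with Elavl2 at -0.22 (SE 0.073), Dpysl3 at -0.15 (SE 0.050) and Dcx, a marker of newborn neurons, at -0.14 (SE 0.070). Neural stem cell markers were higher for 7 of 15 and proliferation genes for 7 of 18 (adjusted p 0.610 and 0.886). CA1 markers were lower for 7 of 10 (adjusted p 0.610), CA2 and CA3 markers for 9 of 14 (0.513), hilar mossy cell markers for 6 of 9 (0.515) and thalamus and habenula markers for 7 of 9 (0.589).

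Glial and vascular markers did not pass either with all libraries. Astrocyte markers were higher for 11 of 15 members (adjusted p 0.422, and 0.0217 without knockout mouse 3), with Ntsr2 at 0.11 (SE 0.043). Reactive astrocyte genes were split 6 to 6 (0.817), microglia markers were higher for 10 of 18 (0.610), oligodendrocyte and myelin genes for 10 of 18 (0.807), oligodendrocyte precursor markers for 7 of 10 (0.807) and endothelial and mural markers for 7 of 16 (0.807). Choroid plexus markers were lower for 6 of 8 (0.593) and meningeal fibroblast markers for 11 of 14 (0.589), where Lum was at 0.43 (SE 0.15).

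Lists tied to irisin and its proposed brain targets showed no call with all libraries. The irisin receptor and PGC-1alpha axis was lower for 11 of 17 members (adjusted p 0.513). Neurotrophin and growth factor signalling was lower for 8 of 14 (0.514), with Bdnf at -0.15 (SE 0.077, 95% interval -0.32 to 0.01) and Ntf3 at 0.21 (SE 0.080). Synaptic vesicle genes were lower for 16 of 22 (0.513), with Sv2b at -0.26 (SE 0.10, and -0.16 without wild-type mouse 1), glutamate receptor and postsynaptic genes for 15 of 26 (0.513) and voltage-gated channels for 22 of 29 (0.155). Voltage-gated channels passed without wild-type mouse 3 (adjusted p 0.0374), knockout mouse 2 (0.0447) or knockout mouse 5 (0.0327). Nuclear-encoded oxidative phosphorylation genes were lower for 39 of 69 (0.589), sterol synthesis genes for 14 of 18 (0.231, and 0.0327 without wild-type mouse 5 or 0.0106 without knockout mouse 4), and interferon-stimulated genes were higher for 10 of 19 (0.762). Glucocorticoid-responsive genes were higher for 10 of 16 (0.513) and circadian clock genes were split 8 to 8 (0.807). Genes next to Fndc5 on chromosome 4 were higher for 18 of 27 (0.355). In none of these 27 lists did a member pass over all genes or adjusted over the list alone. The median, mean and camera direction differed in sign for neural stem cell, interferon, endothelial, clock, reactive astrocyte and proliferation lists.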

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

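The granule marker and label-swap tests below were chosen after the values they use were seen, and the glucocorticoid adjustment after a component of the libraries was seen to follow that list. The count of splits over all gene lists was added after the activity-regulated list was seen to have the smallest p. Of 112 groups of 5 values checked for a library far from its group, 7 were found, against about 5.6 by chance. Granule neuron markers had their lowest list mean in wild-type mouse 1 (-0.160, the other wild types 0.00459 to 0.0653) and, among knockouts, in mouse 1 (-0.0315, the others 0.0413 to 0.0635). Interneuron markers were highest in wild-type mouse 1 (0.209, the others -0.0854 to -0.0113). Astrocyte markers were lowest in knockout mouse 3 (-0.0949) and oligodendrocyte precursor markers in wild-type mouse 3 (-0.142). Rab3c was at 279.8 CPM in knockout mouse 2, the others at 228.6 to 240.3, and Aff3 at 76.7 CPM in knockout mouse 5, the others at 70.5 to 72.3.

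Activity-regulated genes had lower values in the knockout, with an adjusted p of 0.317 in camera with an estimated correlation. A trend with GC content and transcript length is argued against as the whole cause. After its removal the list median was -0.189 (camera adjusted p 2.8e-12, against 9.0e-11 before). A glucocorticoid difference is argued against likewise, since with that list as a covariate the median was -0.166 (camera adjusted p 1.4e-09). These camera values and the splits below used the preset correlation of 0.01 only, and were not repeated with an estimated correlation. A loss of granule neurons as large as the fall was rejected by an exact permutation test (p = 0.00794), with the granule marker mean at 0.03. Killing at different times of day stays open: the 95% interval of Dbp reached 0.482 (log2 fold change 0.20, SE 0.13), beyond the bound of 0.25 set for the clock genes. Of 100 splits of the libraries, 3 gave a camera p for this list as small, the real one included (real 2.7e-12, smallest other 1.7e-15). That argues against chance for this list taken alone but does not exclude it. In 20 of the 100 some list had a p as small (smallest other 1.5e-26), so chance cannot be excluded for the lowest of 33 lists and stays open, beside lower neuronal activity in the knockout and different handling before death.

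Interneuron markers had lower values in the knockout. After removal of the GC and length trend the median was -0.115 (adjusted p 0.000667 with the preset correlation), which argues against that trend as the whole cause. Without that correction the list had an adjusted p = 0.854 with an estimated correlation and 0.809 by fry, so whether it moved at all stays open. Fewer interneurons in the dissected tissue cannot be told apart from lower marker levels per cell: Gad1, Gad2 and Slc32a1 had a mean of -0.10, and an exact permutation test of a fall equal to the list median gave p = 0.976. The pattern leans on wild-type mouse 1, without which the median was -0.06 (adjusted p 0.216).

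Fndc5 reads remained in the knockout. A swap of labels between genotypes is argued against, since the highest knockout library was at 56.7 CPM and the lowest wild type at 69.2 CPM. Reads from exons outside the deleted part may account for the 68.1% that remained, and the counts per gene cannot show it.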

How the results depend on the processing

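The GC and length correction and the removal of the ribosomal RNA precursor were chosen after seeing the data. Fndc5 stayed past the threshold in 20 alternatives, with log2 fold changes of -0.59 to -0.51 and a highest adjusted p of 0.00415. The count of genes was 1 except with the DESeq2 Wald test (3), without wild-type mouse 1 (3), without knockout mouse 2 (2) and with the replicate block (8), and ranged from 1 to 3 when single libraries were left out. Same-numbered mice correlated at 0.445, 0.439, 0.170, 0.00189 and 0.122, so not every pair was above 0.1 and the numbers were not taken to pair the mice. As a hint from the data, wild-type mice 3 and 4 and knockout mouse 4 did not correlate best with their own number and the other 7 mice did. The library labels number the genotypes in alternation but name no shared litter, batch or day, so pairing by number stays open. The block added Cpne7 (adjusted p 8.02e-06, equal to that of Fndc5), Npas4 (0.0362), Rab3c (0.0298), Crhbp (0.0430), Kit, Dgkb and Thsd4 to Fndc5. The cause of the higher counts was not tested. Gene lists past the threshold numbered 6, and 0 with an estimated correlation and 0 by fry's directional test, which use the correlation among list members. The count was 4 after GC and length correction, 5 with no low-count filter and 2 to 7 with single libraries left out; without wild-type mouse 1 it was 2, the activity-regulated and heat shock lists. The activity-regulated list passed in 17 of 19 alternatives, with medians of -0.22 to -0.13. All 17 used camera with the preset correlation, so they do not vary that assumption. The list did not pass in camera with an estimated correlation (adjusted p 0.317) or by fry's directional test (adjusted p 0.285). Chance cannot be excluded for either count: 13 of 100 splits called at least 1 gene (highest other 242, a structure of the samples) and 41 called at least 6 lists (highest other 14), while 26 had at least 935 genes at an unadjusted p under 0.05 (highest other 2813). Over all lists and alternatives 26 calls were lost and 6 gained, and 7 were gained by genes that the naming rule took. Of values past no threshold in either setting, 40 of lists and 4 of genes changed the sign of the value or of its test. At this depth 83.6% of simulated 1.5-fold changes were recovered, and fewer of smaller ones. Those shares hold for many genes changed at once and overstate the recovery where few genes change.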

Other observations

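The tests of Gabra2, of the first component and of the genes around Fndc5 were chosen after these patterns or related values were seen. Gabra2, a GABA-A receptor subunit, differed widely among wild types: mouse 1 was at 295.1 CPM and the other wild types at 113.1 to 157.1 CPM, while knockouts lay between 192.0 and 215.6 CPM. Between genotypes the exact permutation p was 0.198. The log2 fold change was 0.29 (edgeR adjusted p 0.806), and 0.59 (0.00985) without wild-type mouse 1. C57BL/6 substrains are known to differ at Gabra2, and a substrain allele carried by some mice may account for these levels. Such an allele would also differ between the knockouts and the wild types other than mouse 1. Differences in genetic background between the genotypes were tested only around Fndc5. Nnt, which also differs between substrains, varied by only 1.15 times (20.6 to 23.6 CPM), which does not decide the question, since both loci are inherited separately.

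The libraries varied along an axis that did not separate the genotypes. The first principal component, computed from genes outside the lists with a mean above 3 log2 CPM, held 29.5% of the variance (exact permutation p 0.270 for genotype). Over all tested genes it held 18.8% (exact permutation p 0.508). The component without list genes followed the mean of the glucocorticoid-responsive list (Pearson r 0.873, permutation p 0.00055, adjusted p 0.0181 over 33 lists; Spearman rho 0.770, permutation p 0.0120, adjusted p 0.396), with r 0.828 without the 2 extreme mice. Within genotypes r was 0.944 and 0.828. Tsc22d3 ranged from 33.1 to 65.5 CPM and Fkbp5 from 92.8 to 121.3 CPM, the members with the highest r (0.920 and 0.890). Nr3c1 (r -0.854), Pdk4 (-0.771) and Nr3c2 (-0.704) went the other way. The component also followed each library's trend with GC content (Pearson r 0.943, permutation p 5.0e-05; Spearman rho 0.952, permutation p 0.00014; r 0.891 without the 2 extreme mice). Removing what each gene's own GC content and length predict left the spread of the glucocorticoid list at 0.969 of its size. A source behind both the GC trend and the list would escape that correction, so the test does not exclude one. A difference in stress or handling among mice may also be a source of the list's variation. By mouse number, the component was at 5.02 and 6.19 (wild-type and knockout mouse 1), -11.0 and -3.87 (mouse 2), -1.47 and -1.04 (mouse 4) and 2.51 and 2.26 (mouse 5). Mouse 3 went apart, at -4.69 and 6.12. Over genes, same-numbered mice correlated at 0.445, 0.439, 0.170, 0.00189 and 0.122 (mice 1 to 5), which leaves pairing by number open. A source of this component shared by same-numbered mice was not tested beyond that. Whether the component itself is technical stays open.

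DNA kept from a donor strain around Fndc5 was tested by the share of genes with unadjusted p under 0.05 within 5 Mb. It was 5 of 151 (3.31%, exact 95% interval 1.08% to 7.56%), against 6.29% elsewhere, with a one-sided Fisher exact p of 0.963 for a higher share. All 5 were higher in the knockout, at an edgeR adjusted p of 0.788. Tmem39b (log2 fold change 0.23), Ccdc28b (0.13) and Hdac1 (0.12) lay 0.549, 0.481 and 0.389 Mb from Fndc5. Pou3f1 (0.46) and Rspo1 (0.37) lay farther away. The share over the flank does not decide whether the disrupted locus affects these single genes.

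Growth hormone (Gh) had 0 to 286 counts and prolactin (Prl) 2 to 68 counts per library, in both genotypes.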
